A study of Canis lupus familiaris with 16 samples.

How the data were processed

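Genomic DNA of a primary osteosarcoma and of a lung metastasis from each of 8 dogs was measured on 16 arrays for comparative genomic hybridization, in which tumour DNA and normal DNA bind to the same probes under different dyes. Per the labels, 750 ng of tumour DNA carried Cy5 and 750 ng of DNA from normal bone carried Cy3, and the labels of the normal bone repeat the breed, age and sex given for the tumour. Dogs were matched by the sample number in the titles, and the series design states that primaries were compared with matched lung metastases. A correlation of the deviations from the group means gave 0.292 to 0.893 for the numbered pairs.

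The array holds 180880 spots, of which 173934 are not controls. These carry 171534 different probes with a median length of 60 bases and a median spacing of 12651 bp, and 600 of the probes are present as 5 spots. Per the file headers, the images were read with Agilent Feature Extraction 10.7.3.1, which the processing notes of the samples give as 10.7. The deposited processed signals are intensities, from which the authors had subtracted the background, removed a spatial trend and multiplied by 1 dye factor per channel, as a check of the spot values showed. The deposited raw signals and local backgrounds are intensities without correction, per the file headers. The deposited log ratio of each spot is a log10 of Cy5 over Cy3, and the deposited value table of the series holds the same log10 ratio, rounded. The deposited files of dog 5 lack the gene names, which were taken from the file of another dog. The genome build of the probe positions is not given in the sources used here, so positions are those printed in the files.

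Control spots and spots marked as outliers in the files were left out, log2 ratios of the processed signals were averaged over the spots of a probe, and each array was centred on the median of its 162858 autosomal probes. The X chromosome holds 8676 further probes. Probes were summarised as medians in bins of 1 Mb with at least 20 probes (2209 on autosomes and 123 on X) and in bins of 100 kb with at least 5 probes (22674). A bin above 0.25 on the log2 scale counts as gained in a tumour and a bin below -0.25 as lost. Bins of 100 kb at 1 or above count as high gains and those at -1 or below as deep losses. In counts of dogs for these bins, a dog counts if either of its tumours reaches the level. Breakpoints are the steps found by binary segmentation of the 100 kb bins, with a step of at least 0.2, at least 3 bins per segment and a penalty factor of 10.

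The files name 1009 genes, of which 1007 lie on a single chromosome within 3 Mb. A gene's value is the median of the probes in its span with 50 kb on each side, from at least 5 probes, and 1006 genes had a value. These spans are the stretches that the probes of a gene cover in the files, so several are as short as a single probe. Of 162 listed genes, 34 are named in the files and 11 lie within 50 kb of a named gene in the RefSeq gene table and were read there. Another 43 were read over the whole interval of at most 5 Mb between their nearest named neighbours in RefSeq gene order, with a median interval of 2.27 Mb, and 74 were not placed, DLG2 among them. A value from an interval describes the interval and not the gene alone. Among genes given below, this holds for RB1, CD82, RUNX2, CDC5L, PDGFRA, ALPL, LEF1, ARID1A, CDKN1A, PLAU, SPARC, LRP5, GSK3B and JAK2. This way of placing genes was chosen after the file columns were known and before any log ratio was examined.

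Each tissue was compared with normal bone by limma 3.58.1 in R 4.3.3, as a fit of the mean log2 ratio of the 8 dogs against 0, and the metastases were compared with the primaries by limma with the dog as a block. All tests are two-sided. Adjusted p-values follow Benjamini and Hochberg over all bins or over all genes, and the threshold is 0.05. Genes named in the files were adjusted over the named genes, and placed genes over named and placed genes together. For listed genes the count is also given adjusted over the list alone. Values per array, per gene list and per chromosome were tested by exact sign flips of the 8 dogs (256 patterns, smallest p 0.00781), and the likeness of pairs by all ways of pairing the 8 metastases with the 8 primaries. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table in version 1.17.8. Simulated independent bins had the spread between dogs seen in the real bins, and a planted change had the same size in all 8 dogs. The test against normal bone called 55% of 100 bins changed by 0.3 and 96% of 100 changed by 0.6. It made 6 false calls among the unchanged ones of the 2332 bins. The paired test called 69% and 100%, with 9 false calls, and the segmentation found 40 of 40 planted breakpoints and 0 where none were planted.

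The lists of genes, the tests and most alternatives were fixed before the data were examined. The 9 lists cover tumour suppressors, oncogenes, DNA repair, bone formation, metastasis and adhesion, receptor kinase with PI3K and mTOR signalling, Wnt signalling, antigen presentation, and telomere maintenance. No list of cell type markers was used, since the arrays measure DNA. The genes named in the text follow a rule. RB1, CDKN2A, DLG2, MYC, RUNX2 and KIT belong to a set that is named in every comparison. Some results that the rule selects are left out of the text. Against normal bone, the tumour suppressors and the oncogenes each give up to 6 genes past the threshold, by size, or else the 3 largest, and every other list gives its highest and its lowest gene. Between metastases and primaries, listed genes past the threshold are named, or else the 5 highest and the 5 lowest. Called bins that adjoin, with a gap of at most 1 bin, were merged, the values of a merged region are means over its called bins alone, and the 5 highest and 5 lowest merged regions and the 5 most frequent deep losses and high gains are described.

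Alternatives fixed beforehand set the zero level of each array on the mode of its bins or left the arrays uncentred, replaced the processed signals by raw signals corrected with normexp (offset 50), used the value table, kept only the 159382 probes well above background in both channels on every array, changed bins, thresholds, segmentation and gene spans, dropped the dog as a block, and left out each dog in turn. The mode lay -0.18 to 0.13 from the median on the log2 scale. Alternatives by scan day, without dogs 1, 2 and 3, with a loess correction on the GC content of the probe, and with listed genes named in the files alone were added after the data were seen. Precision is limited by the number of arrays, 8 in each group.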

Results

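DNA copy number was measured along the genome in 8 dogs with osteosarcoma, a malignant bone tumour that often spreads to the lung. Each dog contributed 1 primary tumour and 1 lung metastasis, and each was hybridized against DNA from normal bone on its own array. The dogs, 5 male and 3 female, were 5 to 10 years old. Values are log2 ratios of tumour over normal bone, so that 0 stands for the median copy number of the array and a value below 0 for loss. The median Cy5 signal over background was 62.8 to 456 units, and 96.2% to 99.9% of spots were well above background in Cy5. Noise between neighbouring probes was 0.121 to 0.309 on the log2 scale and exceeded 0.25 on an array of dogs 1, 2 and 3. The arrays lay on 6 slides, both arrays of a dog always on the same slide, and were scanned on 2 days, dogs 4 and 8 on the second. The reference DNA of dog 8, a male by its label, had the X chromosome signal of the female dogs, and the X chromosome values of dog 8 rest on that reference.

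The comparison of primaries with normal bone asks which parts of the genome were lost or gained in the tumour of the bone. Primaries had less DNA over most of chromosome 16, from 14000001 to 62000000 bp, where the mean over the called bins was -0.40 (SD 0.19, n = 8) and 7 of 8 dogs lay below -0.25. This region holds NOS3, an endothelial nitric oxide synthase, and DLC1, first described as a gene deleted in liver cancer. Chromosome 18 was lower from 20000001 to 52000000 bp, with a mean of -0.38 (SD 0.19, n = 8) and 6 dogs below -0.25, over HGF, a growth factor, PAX6, a transcription factor, CAT, which encodes catalase, and the cell cycle gene CCND1. The region of chromosome 11 from 42000001 to 50000000 bp, which holds the cell cycle inhibitors CDKN2A and CDKN2B, had a mean of -0.37 (SD 0.22, n = 8), with 7 dogs below -0.25. Shorter regions on chromosome 11 from 11000001 to 14000000 bp and on chromosome 16 from 5000001 to 6000000 bp had means of -0.39 (SD 0.29, n = 8) and -0.37 (SD 0.25, n = 8). These 5 regions had means below 0 under every way of setting the zero level that was tried. A new zero level shifts all regions alike, by little beside these means, so their unchanged sign says little. The region of chromosome 16 from 5000001 to 6000000 bp had -0.42 with the zero level on the mode and -0.35 with uncentred arrays. Of 2332 bins of 1 Mb, limma called 106 lower and 0 higher than normal bone, in 16 merged regions on chromosomes 11, 16, 18, 21 and 38, with a lowest adjusted p of 0.00755 on chromosomes 16 and 18. At an unadjusted p under 0.05 there were 488 bins, 161 of them higher. Losses reached 5 or more dogs in 213 bins and gains in 0 bins, the most frequent gain being shared by 4 dogs. The count was 41 when limma asked for a change beyond 0.1 (treat), and it was 53, 65, 56, 56 and 50 without dogs 2, 3, 4, 5 and 7. It was 0 in the 2 dogs of the second scan day, with 78 bins at an unadjusted p under 0.05, and 0 in the 5 dogs other than 1, 2 and 3, with 369.

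**Figure D1:**
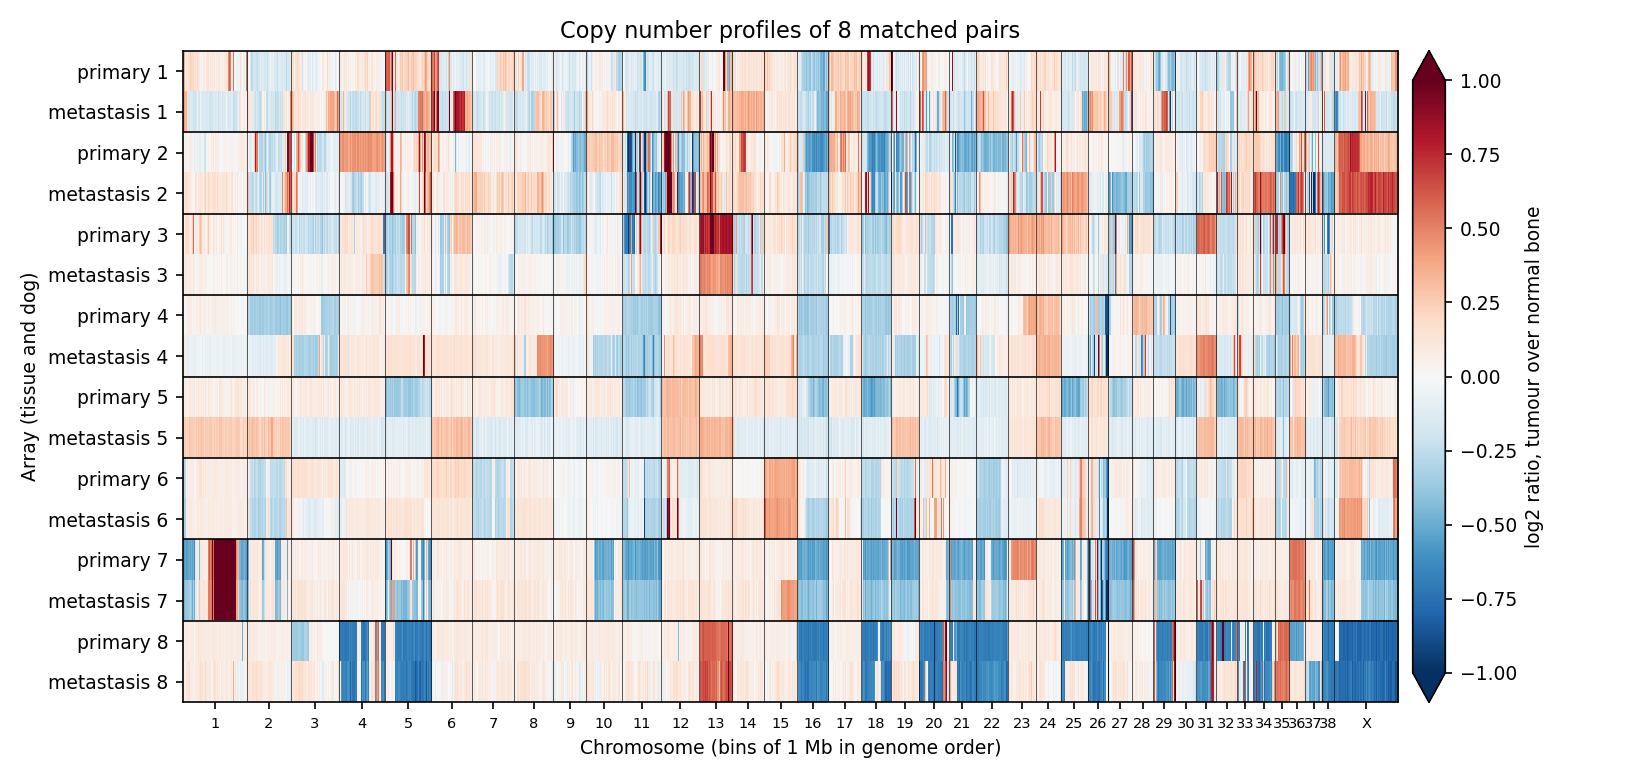
Copy number profiles of the 8 primaries and 8 lung metastases along the chromosomes, as median log2 ratios of tumour over normal bone in 1 Mb bins, with blue for loss and red for gain. Chromosome 16 has a mean of -0.37 in primaries and -0.32 in metastases, and chromosome 13 a mean of 0.26 and 0.29.

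Over whole chromosomes, primaries had the lowest means on chromosomes 16 (-0.37, SD 0.19, n = 8), 18 (-0.33, SD 0.21), 38 (-0.29, SD 0.24) and 21 (-0.27, SD 0.24). The highest were on chromosome 13 (0.26, SD 0.28, n = 8), which carries MYC and KIT, and on chromosomes 24 (0.13), 15 (0.13) and 23 (0.12). Chromosome 13 lay above 0 in 8 of 8 dogs but above 0.25 in 3. In primaries 4, 5 and 7 it stood at 0.054, 0.092 and 0.066. The mode of their bins lay at 0.042, 0.085 and 0.072, so a value above 0 is not a gain there. Of 39 chromosomes, 0 passed the threshold by exact sign flips, with a lowest adjusted p of 0.0508 for 6 chromosomes at the smallest p that 8 dogs allow, and 13 had an unadjusted p under 0.05.

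Among listed genes, the losses of the primaries were deepest at CDKN2A and CDKN2B, inhibitors of cyclin-dependent kinases that lie side by side on chromosome 11. Both were read at the same 16 probes around 44291754 to 44291813 bp, at a mean of -0.80 (SD 0.62, n = 8), with 6 of 8 primaries below -0.25 and adjusted p-values of 0.0296 and 0.0305. CD82, a membrane protein known as a suppressor of metastasis, was read over the interval between ARHGAP1 and CTSD on chromosome 18 at -0.37 (SD 0.24, n = 8, adjusted p 0.0296), with 6 primaries below -0.25. MYC, a transcription factor that drives growth, was above 0.25 in 3 primaries at a mean of 0.45 (SD 0.53, n = 8, adjusted p 0.130).

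Of 15 measured tumour suppressors, 2 were called lower in primaries, CDKN2A and CDKN2B, and 13 did not pass. The list as a whole had a mean of -0.21 (SD 0.13, n = 8), below 0 in 8 of 8 dogs, with an exact sign-flip p of 0.00781 and an adjusted p of 0.0352, and the median of its gene means was -0.10. RB1, read between ATP7B and HTR2A, had a mean of -0.24 (adjusted p 0.148). None of the 12 measured DNA repair genes passed, yet their mean was -0.11 (SD 0.07, n = 8), below 0 in 8 of 8 dogs (exact p 0.00781, adjusted p 0.0352). In that list MRE11, which binds broken DNA ends and was read beside GPR83, had the lowest mean (-0.31, adjusted p 0.0731). The 22 oncogenes had a list mean of 0.07 (SD 0.16, exact p 0.297, adjusted p 0.668) and none passed. The receptor kinase KIT had 0.36 (adjusted p 0.124), and the interval between CNGA1 and KIT, which holds PDGFRA, had 0.34 (adjusted p 0.114). Both list calls ended with the zero level on the mode, where each adjusted p was 0.0703, and the count of called lists was also 0 with the median over genes, with the gene span alone and with genes named in the files alone. The count of called lists was 0 without any 1 dog, since 7 dogs cannot give a smaller p.

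The other 6 lists did not differ from 0 in primaries, with adjusted p-values from exact sign flips of 0.668 to 0.891. The 9 bone formation genes had a mean of 0.03, with the osteoblast regulator RUNX2 highest and the parathyroid hormone receptor PTH1R lowest (-0.13, and -0.06 without dog 8). The interval holding RUNX2 had a mean of 0.33 (SD 0.52, n = 8, adjusted p 0.220), and 0.16 without dog 2. The 11 genes of metastasis and adhesion had a mean of -0.01, although the median of their genes was 0.06, and CD82 was called lower while MMP9, a matrix protease, was highest (0.14). Receptor kinase, PI3K and mTOR genes, 11 in number, had 0.01, with the vascular receptor KDR highest (0.33). The 8 Wnt genes had -0.03, from the interval of the co-receptor LRP5 (-0.26) to that of the kinase GSK3B (0.15). The 6 antigen presentation genes had a mean of -0.01 and a median of 0.01. IRF1, read beside IL5, was lowest (-0.23) and the JAK2 interval highest (0.19, and 0.05 without dog 7). The 3 telomere genes had -0.04 against a median of 0.00, from TERF1 (-0.17, and -0.09 without dog 8) to DAXX (0.04, and 0.01 without dog 2). The sign of DAXX changed with the zero level on the mode, with raw signals corrected by normexp (-0.02) and without dog 5. The sign of the bone formation, adhesion, receptor kinase and antigen presentation lists changed with the way the zero level was set, within -0.06 to 0.05.

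Across 1006 named genes, limma called 37 lower and 0 higher in primaries, of which 19 lay on chromosome 16, 7 on 18, 5 on 11, 4 on 38 and 2 on 21, and 211 had an unadjusted p under 0.05. Of 88 listed genes, 3 passed over all genes and 3 when adjusted over the list alone, namely CDKN2A, CDKN2B and CD82. With raw signals corrected by normexp 7 genes were called higher and 54 lower, and with the gene span alone 17 were called lower. The count was 1, 23, 1, 6 and 1 without dogs 2, 3, 4, 5 and 7, 2 in the dogs of scan day 1, 0 in those of scan day 2 and 0 without dogs 1, 2 and 3, with 180, 90 and 156 genes at an unadjusted p under 0.05. The calls of CDKN2A and CDKN2B ended without each of dogs 1, 2, 4, 5, 6 and 7, and that of CD82 without each of dogs 2, 3, 4, 5 and 7, at adjusted p-values from 0.0566 to 0.124.

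In lung metastases, compared with normal bone to ask what the disseminated tumours carried, chromosome 13 was higher along most of its length. The region from 3000001 to 17000000 bp, with FZD6, a Wnt receptor, and ANGPT1, an angiogenic factor, had a mean over its called bins of 0.32 (SD 0.17, n = 8). The region from 21000001 to 35000000 bp, which holds MYC, had a mean of 0.31 (SD 0.20, n = 8), and that from 57000001 to 66000000 bp, which holds ALB and AFP, 0.31 (SD 0.19, n = 8). The bin from 49000001 to 50000000 bp, inside the interval that holds PDGFRA, had 0.33 (SD 0.20, n = 8), and on chromosome 12 the bin from 16000001 to 17000000 bp, inside the interval that holds RUNX2 and CDC5L, had 0.43 (SD 0.39, n = 8). Each of these 5 regions was above 0 in 8 of 8 dogs and above 0.25 in 4 or 5 of them. A value just above 0 need not be a gain, since 0 is the median of the array. Chromosome 13 as a whole stood at 0.115 and 0.103 in metastases 6 and 7, where the mode of the bins lay at 0.099 and 0.096.

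Among the merged regions that limma called, losses of the metastases were deepest on chromosome 11 from 44000001 to 46000000 bp. This region, over CDKN2A and CDKN2B, had a mean of -0.45 (SD 0.35, n = 8). Chromosome 16 was lower from 15000001 to 62000000 bp at -0.33 (SD 0.15, n = 8), with NOS3 and DLC1, and chromosome 18 from 17000001 to 32000000 bp at -0.32 (SD 0.14, n = 8), with HGF. A second region of chromosome 18 from 39000001 to 52000000 bp, which holds CCND1, had -0.31 (SD 0.22, n = 8), and the bin of chromosome 38 from 25000001 to 26000000 bp, with the IgE receptor gene FCER1A, had -0.32 (SD 0.27, n = 8). The 10 described regions kept their sign under every way of setting the zero level that was tried. A new zero level shifts all regions alike, by little beside these means, so this says little. The bin of chromosome 12 had 0.40 with the zero level on the mode and 0.45 with uncentred arrays. Limma called 143 of 2332 bins, 43 higher and 100 lower, in 8 and 15 merged regions, with a lowest adjusted p of 0.0169, and 476 bins had an unadjusted p under 0.05. Gains reached 5 or more dogs in 20 bins, on chromosomes 13 and X, and losses in 95. The count was 0 with the zero level on the mode, 0 for a change beyond 0.1 (treat), 0 in the dogs of either scan day and 0 without dogs 1, 2 and 3, with 366, 236, 438, 140 and 437 bins at an unadjusted p under 0.05. It was 80, 88, 48, 56, 64 and 78 without dogs 1, 2, 3, 4, 5 and 7, of which 22, 20, 4, 12, 7 and 30 were higher, so that few of the gains remained without dog 3 or dog 5.

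Whole chromosomes of the metastases ran from -0.32 (SD 0.16, n = 8) on chromosome 16, -0.27 on 38, -0.26 on 18 and -0.21 on 11 to 0.12 on 12, 0.13 on 15, 0.14 on 6 and 0.29 (SD 0.17) on 13. None of 39 passed by exact sign flips (lowest adjusted p 0.0609), and 10 had an unadjusted p under 0.05.

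CDKN2A and CDKN2B had a mean of -0.73 (SD 0.49, n = 8) in the metastases, with 6 of 8 below -0.25 and adjusted p-values of 0.0219 and 0.0229. The CD82 interval had -0.33 (SD 0.23, n = 8, adjusted p 0.0389), with 6 metastases below -0.25. MYC was higher at 0.32 (SD 0.25, n = 8, adjusted p 0.0434), with 4 metastases above 0.25. The RUNX2 interval had 0.42 (SD 0.44, n = 8, adjusted p 0.0791) with 4 above 0.25, and it passed with uncentred arrays (0.44, adjusted p 0.0398) and without dog 8 (0.47, adjusted p 0.0436). KIT had 0.22 (SD 0.22, n = 8, adjusted p 0.111).

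Tumour suppressors had a list mean of -0.19 (SD 0.14, n = 8) in metastases, below 0 in 8 of 8 dogs (exact p 0.00781, adjusted p 0.0703). Of their 15 measured members 2 were called lower, while RB1 (-0.12, adjusted p 0.550, and -0.04 without dog 8) did not pass. The 22 oncogenes had a mean of 0.03 and a median of -0.03, and MYC alone was called higher. The 12 repair genes had -0.05, with RAD50, read at the same probes beside IL5 as IRF1, lowest (-0.16). The 9 bone formation genes had 0.01 against a median of -0.05, with the collagen gene COL1A1 lowest (-0.17, adjusted p 0.111). Metastasis and adhesion genes had -0.06, with CD82 called lower and CAV1, which encodes a scaffold of membrane caveolae, highest (0.13). Receptor kinase, PI3K and mTOR genes had -0.03, with the angiogenic factor VEGFA highest (0.29, adjusted p 0.233, and 0.16 without dog 2). Wnt genes had -0.01, from the LRP5 interval (-0.25) to CTNNB1, which encodes beta-catenin (0.13, and 0.07 without dog 2). Antigen presentation genes had -0.01, from IRF1 to the JAK2 interval (0.18, and 0.06 without dog 7). Telomere genes had -0.08, from TERF1 (-0.11, and -0.04 without dog 8) to DAXX (-0.05, and -0.10 without dog 5 but -0.00057 without dog 2). These 8 lists had adjusted p-values from exact sign flips of 0.516 to 0.820. The signs of the oncogene, bone formation, Wnt and antigen presentation lists changed with the zero level.

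**Figure D2:**
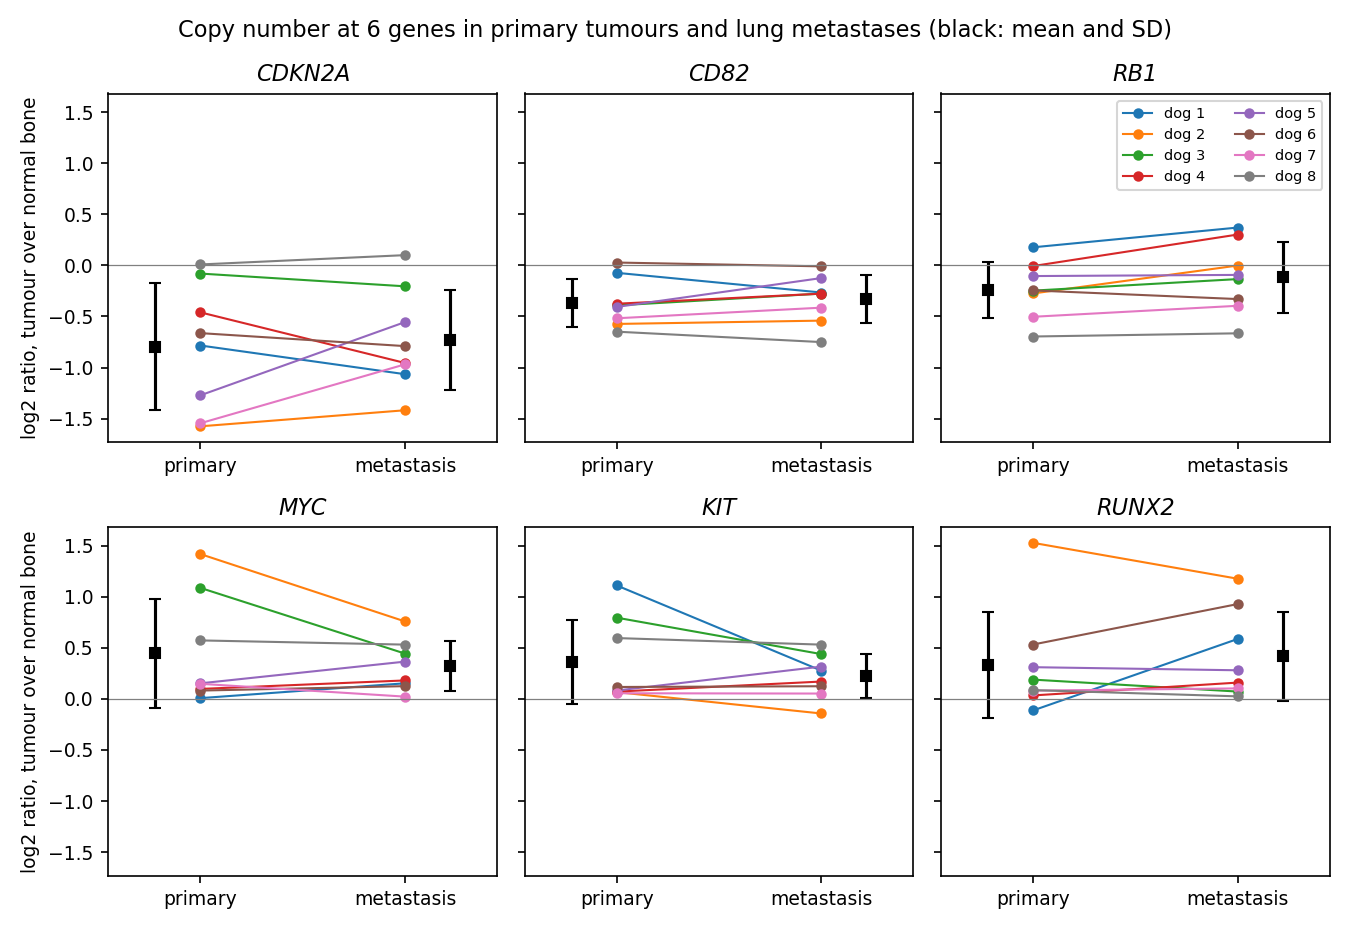
Log2 ratio of named genes in each of the 8 primaries and 8 metastases, with the mean and SD of each group. Values of CD82, RB1 and RUNX2 are those of their intervals. CDKN2A has a mean of -0.80 in primaries and -0.73 in metastases, and MYC 0.45 and 0.32.

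Of 1006 named genes, limma called 17 higher and 25 lower in metastases, and 221 had an unadjusted p under 0.05. Of the 17 higher, 16 lay on chromosome 13. Among 88 listed genes 4 passed over all genes, CDKN2A, CDKN2B, CD82 and MYC, and 6 when adjusted over the list alone, which added CCND1 (-0.31) and the PDGFRA interval (0.25). The count was 0 with the zero level on the mode, 26 with the gene span alone, 1 and 0 in the dogs of scan days 1 and 2, and 0 without dogs 1, 2 and 3, with 197, 147, 178, 66 and 183 at an unadjusted p under 0.05. It was 0, 23, 0, 0, 15, 26 and 22 without dogs 1 to 7, with 205, 200 and 207 at an unadjusted p under 0.05 without dogs 1, 3 and 4. With the zero level on the mode no call remained, and the adjusted p was 0.0535 for CDKN2A, 0.103 for CD82 and 0.104 for MYC. Without a single dog the calls of CDKN2A (dogs 1 and 4), CDKN2B (1, 3 and 4), CD82 (all but 6 and 8) and MYC (all but 7) also ended. CDKN2A and CDKN2B have the same values, and only the set of genes over which each was adjusted differs.

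The comparison of metastases with the primaries of the same dogs is the one the series design names. CDKN2A was below -0.25 in both tumours of 6 dogs and the CD82 interval in both tumours of 5 dogs, and MYC, KIT and the RUNX2 interval were above 0.25 in both tumours of 3 dogs. The mean difference, metastasis minus primary, was 0.06 for CDKN2A (SD 0.41, n = 8), -0.12 for MYC (SD 0.34) and 0.09 for the RUNX2 interval (SD 0.33). The largest positive difference among listed genes was that of the ALPL interval, which holds the alkaline phosphatase gene of bone (0.22, SD 0.18, 6 of 8 dogs higher). Next came the LEF1 interval (0.20, SD 0.45) and MRE11, read beside GPR83 (0.18, SD 0.32). The ARID1A interval (0.14, SD 0.19) and the RB1 interval (0.12, SD 0.13, 7 of 8 dogs higher) followed. The largest negative ones were those of the kinase PIM1 (-0.28, SD 0.50, 0 of 8 dogs higher) and of KIT (-0.14, SD 0.33). The intervals of CDKN1A (-0.17, SD 0.44), PLAU (-0.15, SD 0.27) and SPARC (-0.14, SD 0.27) were also among them. The CDKN1A interval ends at PIM1 on chromosome 12, so these 2 values describe adjoining DNA. Without dog 2 the differences were -0.11 for PIM1, -0.02 for CDKN1A, -0.06 for PLAU, -0.07 for SPARC and 0.09 for LEF1, and KIT had -0.04 without dog 1. MRE11 had 0.12 without dog 2 and 0.11 without dog 8, MYC -0.05 without dog 2 and -0.05 without dog 3. The sign changed for CDKN2A without dog 5 (-0.03) and without dog 7 (-0.01) and for the RUNX2 interval without dog 1 (-0.0023).

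None of these differences passed. With the dog as a block, limma called 0 of 1006 genes (33 at an unadjusted p under 0.05, lowest adjusted p 0.912) and 0 of 88 listed genes, also when adjusted over the list alone, where ALPL was the 1 gene at an unadjusted p under 0.05 (lowest adjusted p 0.527). Over 2332 bins limma with the block called 0, with 99 at an unadjusted p under 0.05 and a lowest adjusted p of 0.762. Without the dog as a block it called 0 bins and 0 genes as well, with 20 and 7 at an unadjusted p under 0.05. The bins with the largest differences were those of chromosome 34 from 7000001 to 8000000 bp (0.32, SD 0.59, n = 8), of chromosome 32 from 37000001 to 38000000 bp (0.30, SD 0.30, higher in 8 of 8 metastases) and of chromosome 12 from 11000001 to 12000000 bp (-0.30, SD 0.63). By chromosome, the exact sign flips called 0 of 39, with 2 at an unadjusted p under 0.05. Chromosome 8 was higher in 8 of 8 metastases at 0.12 (SD 0.10, n = 8, exact p 0.00781, adjusted p 0.305) and chromosome 22 in 6 of 8 at 0.11 (exact p 0.0391, adjusted p 0.740), while chromosome 25 had the highest mean (0.14) and chromosome 28 the lowest (-0.09). Of the 9 lists 0 passed, with the largest difference in DNA repair at 0.06 (SD 0.06, 6 of 8 dogs higher, exact p 0.0547, adjusted p 0.492), and 0.06 and 0.05 in the dogs of scan days 1 and 2. The other 8 lists had differences from -0.05 for oncogenes to 0.02 for Wnt genes and tumour suppressors, at adjusted p-values of 0.753 to 0.859, and the signs of the antigen presentation and telomere lists changed with the scaling.

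To ask whether a metastasis resembles the primary of its own dog, bin profiles were correlated between all primaries and all metastases, across the 2209 autosomal bins, which are not independent of each other. Matched profiles had a mean Pearson r of 0.645 (SD 0.233, n = 8) and unmatched ones 0.210, a difference of 0.435. No other pairing of the metastases with the primaries gave as large a mean (exact permutation p 2.48e-05, the smallest possible). Matched r was highest in dogs 7 (0.940), 6 (0.850) and 8 (0.832) and lowest in dog 1 (0.294). Each of the 8 primaries was most like its own metastasis, and 7 of 8 metastases were most like their own primary, the exception being metastasis 1, which had 0.310 with primary 5. With rank correlations 6 of 8 primaries were most like their own metastasis, at a difference of 0.344 (exact permutation p 2.48e-05). The difference was 0.439 in the 6 dogs of scan day 1 (exact permutation p 0.00139) and 0.439 in the 2 dogs of scan day 2, which cannot reach the threshold. Primary and metastasis differed by more than 0.25 in 2.40% of bins in dog 6, 7.06% in dog 7, 10.1% in dog 8, 20.5% in dog 3, 23.0% in dog 5, 23.5% in dog 4, 31.8% in dog 1 and 39.1% in dog 2.

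**Figure D3:**
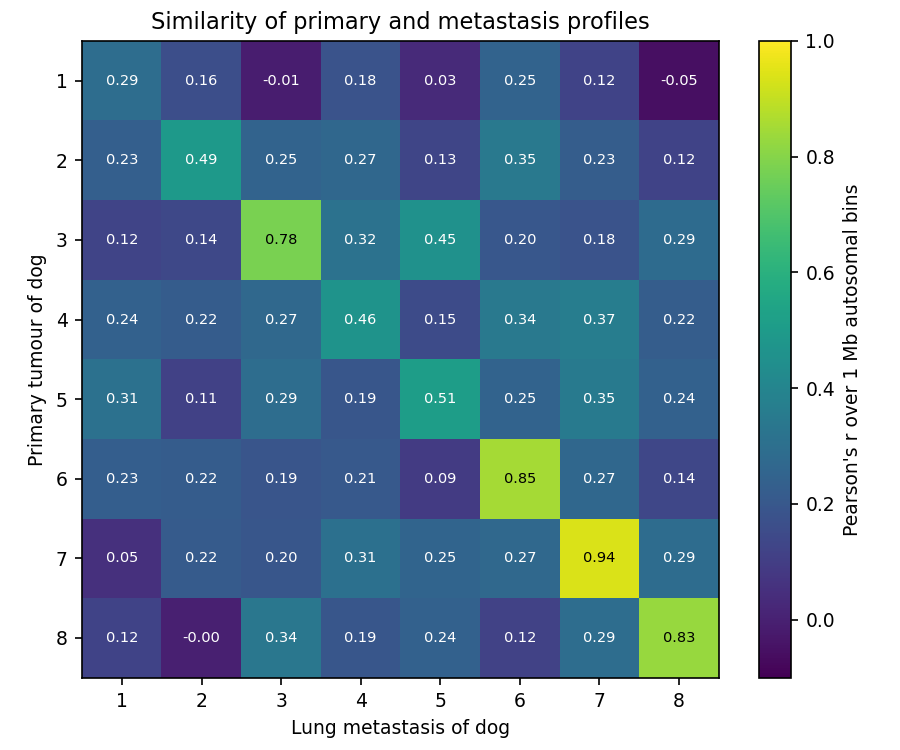
Pearson correlation across autosomal 1 Mb bins between each primary and each lung metastasis, with matched pairs on the diagonal. Matched pairs range from 0.294 to 0.940 and unmatched ones from -0.05 to 0.454.

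The extent of copy number change was compared within dogs to ask whether metastases carry more of it. Primaries had 21.6% of autosomal bins lost (SD 8.18, n = 8) and 8.43% gained (SD 5.00, n = 8), and metastases 17.4% lost (SD 10.4, n = 8) and 11.8% gained (SD 7.51, n = 8). The paired difference was -4.20 points for losses (exact p 0.359) and 3.40 points for gains (exact p 0.266). Gains were more extensive in 6 of 8 metastases. Losses were more extensive in 5 of 8, against the sign of their mean difference. Dog 5 stood apart in both, with losses of 24.2% and 0.136% and gains of 3.53% and 24.0% in its primary and metastasis. Altered bins made up 30.0% (SD 9.43) and 29.2% (SD 8.01, exact p 0.875). The SD of a profile, a measure that tumour content and ploidy also move, was 0.274 (SD 0.0868) and 0.259 (SD 0.0759, exact p 0.578). Profiles had 44.6 breakpoints in primaries (SD 30.0, n = 8) and 52.4 in metastases (SD 34.1, n = 8, exact p 0.406). None of these measures differed between the tissues by exact sign flips within dogs. Without the pairing of the dogs the exact permutation p was 0.857 for altered bins, 0.294 for gains, 0.381 for losses, 0.716 for the SD of a profile and 0.639 for breakpoints. In dogs of scan days 1 and 2 the difference was -4.93 and -2.01 for losses, 3.70 and 2.49 for gains and 4.33 and 18 for breakpoints, and with only 6 and 2 dogs the smallest possible p was 0.0313 and 0.5. The direction depended on the settings. With a threshold of 0.35 losses were less extensive in 7 of 8 metastases (-4.61 points, exact p 0.0156), while with a threshold from the bin noise of each array they were more extensive in 6 of 8 (6.55 points, exact p 0.234) and gains differed by -0.11 points (exact p 0.961). Without dog 3 gains were more extensive by 5.35 points (exact p 0.0313, n = 7), and without dog 5 the difference was 0.957 points for gains and -1.36 for losses. The difference in altered bins ran from -3.77 to 6.45 points over the alternatives, that in the SD of a profile was 0.00352 with raw signals corrected by normexp, and that in breakpoints was 1.75 with a step of at least 0.3.

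**Figure D4:**
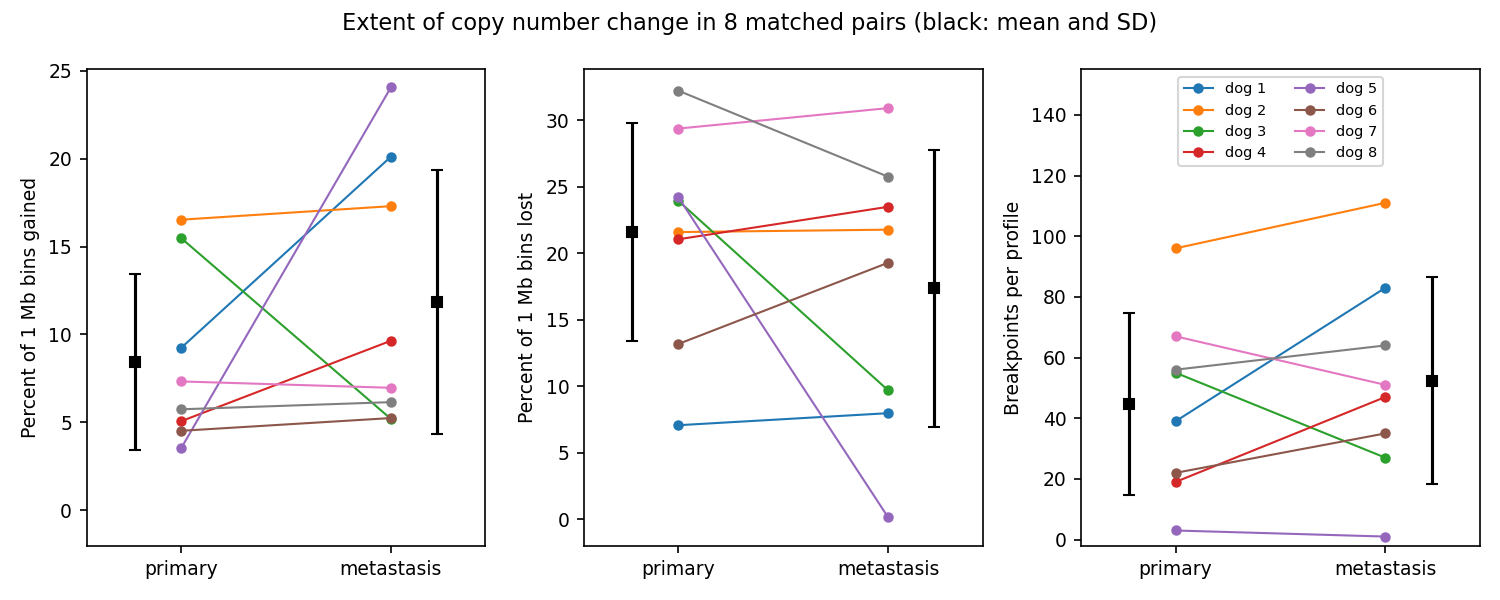
Percent of autosomal 1 Mb bins gained, percent lost and number of breakpoints in the primary and the lung metastasis of each dog, joined by lines, with mean and SD in black. Means are 8.43 and 11.8% gained, 21.6 and 17.4% lost, and 44.6 and 52.4 breakpoints.

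Focal changes were sought in 100 kb bins, and the most frequent deep losses included the cell cycle inhibitor CDKN2B. Chromosome 11 from 44000001 to 44800000 bp, with CDKN2B, reached -1 or below in 4 dogs, in 4 primaries and 2 metastases at its peak, which had means of -0.93 (SD 0.69, n = 8) and -0.80 (SD 0.53, n = 8). On chromosome 21, bins from 17500001 to 17700000 bp and from 17900001 to 18100000 bp were deeply lost in 3 and 2 dogs, at means of -0.84 and -0.89 in primaries and -0.50 and -0.75 in metastases. They lie between TYR and CLNS1A, an interval with 44 protein-coding genes in RefSeq, the synaptic scaffold gene DLG2 among them, a lookup made after the bins were seen. Part of DMD, the dystrophin gene on X from 27300001 to 27500000 bp, was deeply lost in dogs 1, 2 and 8, and the values of dog 8 there, -2.93 in both tumours, rest on a reference with the X chromosome signal of the female dogs.

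A high gain in 3 dogs lay on chromosome 13 from 48800001 to 49000000 bp, in the interval between CNGA1 and KIT that holds PDGFRA. At its peak, a bin of 6 probes, the primaries of dogs 1 and 3 had 1.26 and 1.01. The metastasis of dog 2 had 1.09 there. No dog reached 1 in both tumours, and each of these arrays had a probe noise above 0.25. Another in 3 dogs lay on chromosome 12 from 15300001 to 15900000 bp, near the angiogenic factor VEGFA and the nucleoside transporter SLC29A1. Its peak, from 15700001 to 15800000 bp, lay between SLC29A1 and PLA2G7, in the interval that holds RUNX2 and CDC5L. The third in 3 dogs lay on chromosome 5 from 14300001 to 17000000 bp, between B3GAT1 and CD3E. At the peaks on chromosomes 12 and 5, 1 dog each reached 1 in both tumours. The peaks on chromosomes 13, 12 and 5 had means of 0.48, 0.31 and 0.30 in primaries and 0.50, 0.50 and 0.38 in metastases. High gains in 2 dogs lay on chromosome 12 from 16300001 to 16400000 bp, in the interval that holds RUNX2, and on chromosome 13 from 25600001 to 25700000 bp, between ANXA13 and MYC. Each was reached in 1 primary and in 1 metastasis of another dog. Deeply lost autosomal bins numbered 32.9 per primary (SD 34.9, n = 8) and 45.2 per metastasis (SD 38.5, n = 8, exact p 0.242), a difference of 12.4 that was 4.00 and 37.5 in the dogs of scan days 1 and 2, 20.6 with the zero level on the mode and 28.4 with raw signals corrected by normexp. Highly gained bins numbered 123 (SD 147) and 108 (SD 132, exact p 0.547), a difference of -14.6 that was -15.7 and -11.5 in the dogs of scan days 1 and 2. It was -2.88 with the zero level on the mode, and its sign changed with raw signals corrected by normexp (18.5, exact p 0.328). Without the pairing of the dogs the exact permutation p was 0.512 for deep losses and 0.831 for high gains.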

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

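Of the tests in this part, that of unmatched pairs on a slide, those of the primary of dog 8 alone, the probe fingerprints and that of GC content in dog 5 were chosen only after the result was seen.

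The 12 values given here were singled out because 1 dog lay far from the others of its group in Dixon's test, among 123 groups tested, and chance alone does this in about 1 of 20 groups. The reference channel of dog 8, labelled male, had an X chromosome signal of -0.0287 relative to the autosomes on the primary array and -0.0337 on the metastasis array, against -0.74 or lower in the other males. The JAK2 interval stood at 1.12 in the primary and 1.04 in the metastasis of dog 7. The RUNX2 interval stood at 1.53 in the primary of dog 2, the GSK3B interval at 0.49 in the primary of dog 1, and PTH1R at -0.60 in the primary of dog 8. The LRP5 interval stood at -0.76 in the metastasis of dog 8. The difference between metastasis and primary of dog 2 was -1.50 for PIM1, -1.17 for the CDKN1A interval and -0.76 for the PLAU interval. The CDKN1A interval ends at PIM1, so the values of PIM1 and CDKN1A describe adjoining DNA. The reliability of the bin values, from a split of the probes, was 0.957 in the primary of dog 1, with 0.981 as the next lowest.

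Matched primaries and metastases were more alike than unmatched ones, by 0.435 in mean r. The tables argue against the shared reference DNA of a dog as the cause, since with references of other dogs, none shared between the sides, the difference was 0.447 (matched 0.645, unmatched 0.198). They also argue against the shared slide, since the 4 unmatched pairs on a slide had a mean r of 0.234, far below the matched mean. A common origin of both tumours of a dog is a candidate explanation and was not tested further. Inherited copy number differences of a dog stay open too where its reference DNA is not its own.

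The reference of dog 8 has the X chromosome signal of the female dogs, which might mean DNA from another dog, or a wrong sex label with an X copy lost in both tumours. The test uses the first 6000000 bp of X, which both sexes hold in equal copies, and takes the tumour ratio of that part minus the rest of X. The primary had 0.789, against the loss of a whole X copy in that tumour. The metastasis had 0.0728, with both parts of X low, at -0.69 in the first part and -0.77 in the rest. This value cannot decide, since DNA of another dog gives it too if the first part was lost there as well. Such a loss was not tested. Probe residuals of the tumours of dog 8 correlated at 0.435 with the reference on its other array. With the references of other dogs they reached at most 0.242, the value for dog 4, which was scanned on the same day. Among references of other dogs, the tumours of dog 4 were likewise closest to that of dog 8. The residuals were most like a dog's own reference in dogs 4 to 8, but not in dogs 1, 2 and 3. Both arrays of dog 8 share a slide with no other dog. Effects of slide and scan day are therefore not separated from a match with its own DNA. The residuals cannot decide, and both explanations stay open.

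The profile of dog 5 has 3 breakpoints in the primary and 1 in the metastasis, with 91.7% and 95.6% of its bin variance between chromosomes, and its losses lie in the primary and its gains in the metastasis. The tables argue against a wave of GC content, since the larger r of its bins with probe GC was 0.0666. With the zero level on the mode, the difference between its arrays in percent gained minus percent lost was 57.7 points against 44.6, or 129% of its size. The mode lay 0.085 from the median in the primary and -0.115 in the metastasis. Median and mode both set zero at a common level of the array. The test therefore cannot decide whether that level was the normal copy number, and a misplaced zero level stays open. Changes of whole chromosomes in number are a candidate explanation, which no count of chromosomes was at hand to test.

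Chance assignment was tested with 100 sign flips of the dogs, or swaps of the tissues within dogs, the real one included, by refitting limma each time. For bins of the primaries 1 of 100 gave as many calls, the real one, with 106 against at most 40 in the others, and for bins of the metastases 1 of 100, with 143 against at most 0. For genes of the primaries 1 of 100 gave as many, with 37 against at most 4, and for genes of the metastases 1 of 100, with 42 against at most 0. Chance alone is an unlikely source of these 4 counts. For metastases against primaries the real counts were 0, so 100 of 100 swaps had to give as many bins and 100 of 100 as many genes (at most 0 in the others), which decides nothing. At an unadjusted p under 0.05, 39 of 100 swaps gave at least the real 99 bins, with up to 239, and 54 of 100 at least the real 33 genes, with up to 100, so chance cannot be excluded for these.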

How the results depend on the processing

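The alternatives by scan day, without dogs 1, 2 and 3, with the GC correction of probes and with listed genes named in the files alone were chosen only after the results were seen.

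Of 352 alternatives for the comparisons 293 stayed on the same side of the threshold, or within 1.5 times of a count, and 0 passed it in the opposite direction. Of 854 for named genes 813 stayed on the same side, 39 lost a call and 2 gained one. Differences that had not passed did change sign, in 14 of 126 alternatives for the measures per array and the likeness of pairs, and in 6 of 854 for named genes. With a threshold from the bin noise the share lost differed by 6.55 points and the share altered by 6.45, and with normexp the highly gained bins by 18.5. The count of 0 for metastases against primaries held in bins, genes, lists and chromosomes under every alternative run, and the likeness of matched pairs stayed between 0.344 and 0.486. For lists and chromosomes, runs with fewer dogs could call little or nothing. Exact sign flips cannot give a p below 0.0313 with 6 dogs or below 0.5 with 2. Those counts of 0, which are also among the 293, therefore say little.

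With the zero level on the mode the calls in metastases were 0 bins and 0 genes, and the called lists of the primaries 0. With treat at 0.1 the bins were 41 in primaries and 0 in metastases. Raw signals with normexp gave 61 genes in primaries (7 higher and 54 lower, against 0 and 37). The gene span alone, which leaves 607 genes to test, gave 17 genes in primaries, 26 in metastases (10 higher and 16 lower, against 17 and 25) and 0 lists in primaries. Lists in primaries were also 0 with the median over genes and with genes named in the files alone. With a threshold of 0.35 the share lost differed by -4.61 points (exact p 0.0156). Apart from the tests with fewer genes or dogs, the cause was not tested.

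In the dogs of scan day 1 the calls were 0 bins in metastases, 2 genes in primaries, 1 gene in metastases and 0 lists in primaries. In the 2 dogs of scan day 2 they were 0 bins, 0 genes and 0 lists in either tissue, and the likeness of pairs was 0.439 with an exact permutation p of 1. Without dogs 1, 2 and 3 they were 0 bins, 0 genes and 0 lists in either tissue. Smaller numbers of dogs raise the smallest p and widen the error by construction.

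Leaving out each dog in turn gave 50 to 120 bins and 1 to 42 genes in primaries, 48 to 143 bins and 0 to 33 genes in metastases, 0 to 0 lists in primaries, and 0.957 to 5.35 points for the share gained, the last without dog 3. A GC correction with the genome around each probe was not run, since no genome of the build of the files was used here. Signal over background limits the faintest arrays most, as 96.2% of spots were well above background in Cy5 in the primary of dog 1, against 99.9% in both tumours of dog 4.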

Other observations

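The genes outside the lists, the neighbours of focal changes and the comparison of the sexes in this part were chosen only after the data had been examined.

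Among genes in no list, the called losses of both tissues took in IL3 and CSF2 on chromosome 11, while IL5 near them was not called in either tissue. IL3, a growth factor of blood progenitors, had a mean of -0.37 (SD 0.24, n = 8, adjusted p 0.0305) in primaries and -0.33 (SD 0.22, n = 8, adjusted p 0.0360) in metastases, and its neighbour CSF2 -0.34 (SD 0.22, n = 8, adjusted p 0.0305) and -0.31 (SD 0.21, n = 8, adjusted p 0.0374). On chromosome 16, NOS3 had -0.40 (SD 0.21, adjusted p 0.0216) and -0.44 (SD 0.21, adjusted p 0.0229), and DLC1 was below -0.25 in 7 primaries and 7 metastases, at -0.40 (adjusted p 0.0216) and -0.36 (adjusted p 0.0229). On chromosome 13 the Wnt receptor FZD6 was above 0.25 in 6 metastases at 0.33 (SD 0.15, n = 8, adjusted p 0.0229), and GNRHR, the receptor of a reproductive hormone, in 5 at 0.35 (SD 0.24, n = 8, adjusted p 0.0360). ASB17 on chromosome 6 was the called gain of the metastases outside chromosome 13, at 0.22 (SD 0.09, n = 8, adjusted p 0.0391).

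The stretch of chromosome 21 between TYR and CLNS1A, whose interval in RefSeq gene order holds DLG2, reached -2.004 in the primary and -1.50 in the metastasis of dog 2 and -1.76 and -1.22 in those of dog 7, at 17600001 to 17700000 bp. At 17900001 to 18000000 bp it reached -3.20 and -2.84 in dog 8.

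The difference between metastasis and primary was compared between 5 male and 3 female dogs in 12 measures per array, with dog 8 among the males by its label, which the X chromosome signal of its reference leaves in doubt. The lowest adjusted p by exact permutation was 0.6, and gains were 6.65 points more extensive in the metastases of males and -2.02 points in those of females (exact permutation p 0.214, where 0.0357 is the smallest possible).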
